A study of Mus musculus with 12 samples.

How the data were processed

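H3K36ac, the acetylation of lysine 36 on histone H3, was profiled by chromatin immunoprecipitation and sequencing in liver tumours of mice treated with anti-PD-1. The 12 samples were 3 H3K36ac immunoprecipitates and 3 inputs from LysM-Cre mice, which carry the myeloid Cre driver alone, and the same numbers from mice lacking Trem2 in myeloid cells (Trem2-MKO). A peak list was used for each of the 6 immunoprecipitates, and the 6 inputs were not analysed here as libraries of their own. Per the labels' protocols, tumour was ground in liquid nitrogen and fixed with formaldehyde, chromatin was sheared on a Covaris instrument, and the precipitated DNA went through whole-genome amplification before library preparation. Amplification copies fragments unevenly, which can add local pileups that are not histone signal.

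Per the submitters' processing notes, the tools were Trimmomatic, Bowtie2, SAMtools, Picard, MACS2 and deepTools and the genome build was mm10; versions were not given in the sources used here. The names of the deposited lists state that alignments were sorted, that duplicates were removed, and that peaks of each library were called against a pooled control with a p-value limit of 0.01, a cap of 500000 peaks and a final filter. Each deposited list gives, per peak, an integer score, a fold enrichment over the local background, a −log10 p-value, a −log10 q-value and the offset of the summit. The authors' fold and p-values belong to single peaks and were used here to describe, rank or filter peaks within a list. The peak numbers skipped in the lists came to between 6 and 17 per library. No list held overlapping intervals, so the number of peaks stayed as deposited after overlapping intervals were merged.

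Read totals were not used here, so depth was recovered from the peaks themselves. A whole number of fragments at the summit and a Poisson background were sought that returned both the fold, taken as (pileup + 1)/(background + 1), and the p-value of each peak. All peaks were solved in every library, within 0.0002 on the −log10 scale in 4 libraries and within 0.005 in Trem2-MKO replicates 2 and 3, where the pileup had been scaled by 0.903 and 0.798. The mean control depth per 10 kb was taken from the unit in which the local backgrounds above the lowest were whole control counts. A first fit, which allowed counts per 10 kb only and a tolerance of 0.04 of a count, gave units that differed between libraries of a genotype. After its result was seen, counts over the fragment length (taken as the smallest peak width) were allowed too and the tolerance was set to 0.02. With these, 100% of these backgrounds fell on the grid in every library, against 64.1% to 85.4% for the next best unit. The recovered control depth was 106 fragments per 10 kb in the 3 LysM-Cre libraries and 144 in the 3 Trem2-MKO libraries. The precision of a peak follows from these counts: the median summit held 11 fragments in 4 libraries, 20 in Trem2-MKO replicate 2 and 23 in replicate 3.

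Gene positions came from an NCBI RefSeq table of GRCm38.p6, the assembly that mm10 names, with 21883 protein-coding genes on chromosomes 1 to 19, X and Y. Some entries, such as Ren2 at 159748 to 169505 on chromosome 1, may carry positions on sequences outside the main chromosomes. They were kept, which would lower the shares of all genes marked. The table used here holds neither strand nor exons, so the planned window around the transcription start could not be placed. Windows of 1 kb either side of both annotated ends of a gene were used in its place and are called gene-end windows; they contain the start. Exon, intron and untranslated region were not assigned.

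The peaks of the 6 lists were merged where they overlapped by 1 bp or more, and each union region was scored for the libraries with a peak in it. A region was called genotype-specific when 3 of 3 libraries of one genotype and 0 of 3 of the other had a peak; genes were scored in the same way over their gene-end windows. Means of the genotypes were compared by exact two-sided permutation tests over the 20 assignments of the libraries, where p cannot go below 0.1, so that no comparison between the genotypes could reach 0.05 by this test; tests that assume a distribution were not used. Fisher's exact tests were two-sided. Pairwise overlap was the Jaccard index of base pairs, ranked among the 10 splits of the libraries into 3 and 3. For 24 gene lists with 531 distinct genes found in the table (4 of 549 entries were not matched), the log2 odds ratio of list genes against other genes having a gene-end peak was taken per library, with 0.5 added to each cell, and p-values were adjusted by Benjamini-Hochberg. Labels call the libraries replicates without saying that each came from its own mouse, although the labels' design text counts 3 mice per genotype.

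Chance levels were set in 2 ways. The planned expectation multiplied each library's share of union regions or of genes. After the data were seen, a second expectation was added, because union regions hold a peak by construction and this raises the planned value for regions: every peak was moved by a random distance of 20 to 500 kb in either direction, 100 times, which keeps broad regional density and breaks exact positions. Moved peaks can land in unmappable sequence, which lowers this expectation somewhat by an unknown amount. The recovery of depth, the random placement of fragments, the distances of summits from gene ends, the chromosome profiles and the overlap difference in moved lists were also added after the data were seen.

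Genes named in the text followed a rule fixed before the data were examined: Trem2, Lyz2 and Pdcd1; per genotype up to 10 genotype-specific genes by the mean percentile of their best peak's p-value; up to 10 genes marked in all 6 libraries; and up to 4 members per list with the largest difference in marked libraries. Up to 5 regions per genotype were named by the same percentile. Items named outside this rule are said to have been chosen after their values were seen. Alternatives were a −log10 p of at least 5, a −log10 q of at least 2, the 4638 strongest peaks of each list, merging within 500 bp, an overlap of at least 50% of the shorter peak, summits ± 100 bp, windows of 2.5 kb, whole gene bodies, a block by replicate number, and leaving out each library.

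The steps were tested on simulated lists with as many peaks as the real ones: 60 of 60 planted LysM-Cre regions and 30 of 30 planted Trem2-MKO regions were found, with 61 and 30 regions called. Simulated pileups were recovered in 100% of cases. Of 200 random gene lists in the simulated libraries, 14% put the genotypes apart, above the nominal 10%. The recovery of the control depth was not tested on simulated data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9.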

Results

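The data were 6 lists of H3K36ac peaks, each called on a single liver tumour library, from 3 LysM-Cre and 3 Trem2-MKO mice after anti-PD-1 treatment. H3K36ac is a histone mark found mainly at promoters of active genes. Anti-PD-1 is an antibody that blocks an inhibitory receptor of T cells, and TREM2 is a lipid-sensing receptor of macrophages. The comparison asked whether loss of Trem2 in myeloid cells goes with a different distribution of H3K36ac in treated tumours. Whole tumour was profiled, so hepatocyte-lineage, stromal and immune chromatin all contributed to each list.

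The knocked-out gene itself carried no peak. Trem2 (chromosome 17, 48346401 to 48352276, mm10) had a peak in 0 of 6 libraries in its gene-end windows and in its body, and Lyz2, the lysozyme M gene after which LysM-Cre is named, had 0 of 6 in both as well. With windows of 2.5 kb, a peak lay near Trem2 in 2 of 3 LysM-Cre and 0 of 3 Trem2-MKO libraries. Pdcd1, which encodes PD-1, had 0 of 6 at its gene ends and 1 Trem2-MKO library with a peak in its body. Peak lists of whole tumour do not show whether the gene was deleted in myeloid cells, so the labels could not be checked this way.

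LysM-Cre tumours had 18262, 29970 and 19981 peaks (22738 ± 6322, SD, n = 3), and Trem2-MKO tumours had 29906, 6840 and 4638 (13795 ± 13996, SD, n = 3). The mean was 1.65-fold higher in LysM-Cre, a difference smaller than the spread of the Trem2-MKO libraries (exact two-sided permutation p = 0.3). Peaks covered 10.4 ± 2.14 Mb in LysM-Cre and 6.19 ± 5.78 Mb in Trem2-MKO (exact two-sided permutation p = 0.4, n = 3 per genotype). Peaks were weak in both genotypes: the median fold over background lay between 2.63 and 3.25, and 9.47% to 17.1% of the peaks of a library had a q-value of 0.01 or less.

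The low counts of Trem2-MKO replicates 2 and 3 came with the deepest immunoprecipitates. Recovered depth was 160 and 181 fragments per 10 kb in these libraries, above their control at 144, and their recovered pileup scales were 0.903 and 0.798, against 1 elsewhere. The other 4 libraries had 61.3 to 79.5 fragments per 10 kb, below their controls. With the 4638 strongest peaks of each list, the difference in covered length changed sign, to −0.0348 Mb.

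**Figure D1:**
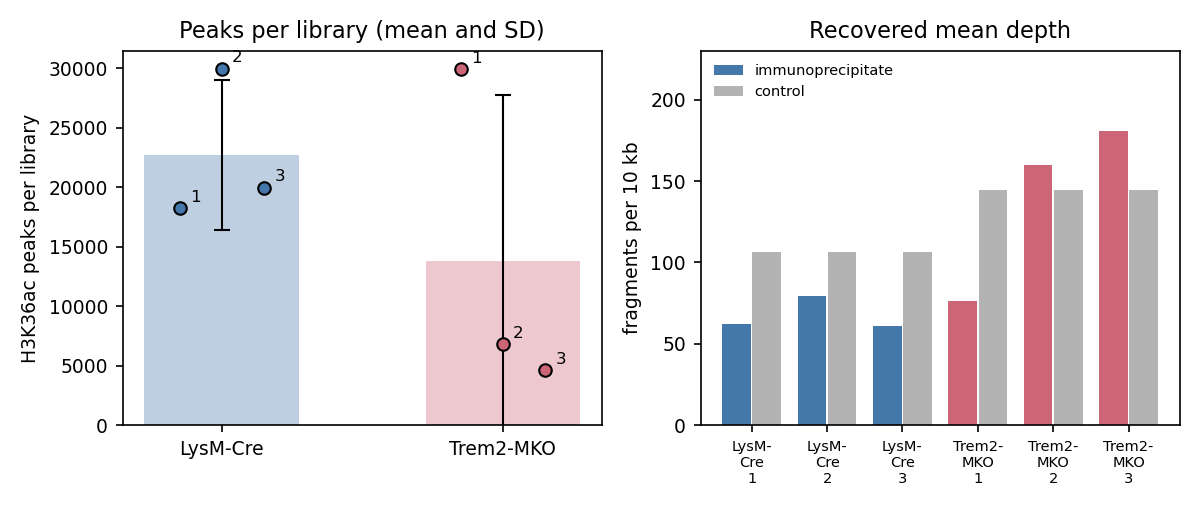
Left, H3K36ac peaks per library (points, numbered by replicate) with the mean (bar) and SD (line, cut off at 0 for Trem2-MKO) of 3 libraries per genotype. Right, mean fragments per 10 kb of each immunoprecipitate and its control, recovered from the fold and p-value of the peaks; Trem2-MKO replicates 2 and 3, with 6840 and 4638 peaks, were the deepest at 160 and 181.

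Most peaks were called in a single library. Peaks were weak and absence of a peak does not show absence of the mark, so these peaks cannot be called particular to a tumour. Of 104601 union regions, 95.6% held a peak of 1 library, 4300 of 2 libraries, 305 of 3, 23 of 4 and 3 of 5, and none was found in all 6. Moved lists gave 1895 regions in 2 libraries and 29.6 in 3, so sharing was above chance although rare. The 3 regions in 5 libraries lay in Olfm3, an olfactomedin-family gene (chromosome 3, 114906959 to 114907452), 23.9 kb from Hao2, a peroxisomal hydroxyacid oxidase gene (chromosome 3, 98919258 to 98919960), and 1091 kb from Nudt12 (chromosome 17, 60103927 to 60104763); these regions were chosen after their values were seen.

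Tumours of the same genotype shared more of their peaks than tumours of different genotypes. The mean Jaccard index was 0.834% within genotypes (range 0.534% to 1.03%) and 0.461% between them (0.311% to 0.661%), a difference of 0.373 percentage points. It was the largest of the 10 splits, which gives an exact one-sided p of 0.1, the smallest that 10 splits allow. The next largest split, LysM-Cre replicate 1 with Trem2-MKO replicates 2 and 3 against the rest, gave 0.162. Counted against moved lists, the overlap was 2.94 to 11.7 times the expectation within genotypes and 1.87 to 4.53 times between them. The highest value belonged to Trem2-MKO replicates 2 and 3, with 151 overlapping peaks where 12.9 were expected, and the 3 LysM-Cre pairs, at 2.94 to 3.03, lay below 3 of the 9 pairs between genotypes.

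**Figure D2:**
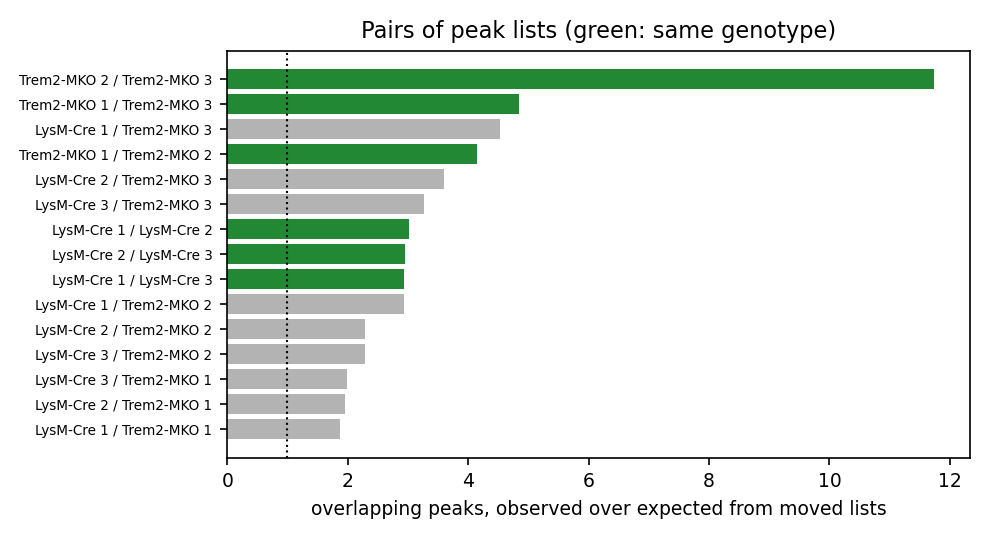
Observed over expected overlap for each of the 15 pairs of peak lists, the expectation coming from 100 draws of moved peaks; the dotted line marks 1 and green bars are pairs of the same genotype. The lowest value was 1.87, and the largest value, 11.7, was that of Trem2-MKO replicates 2 and 3.

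In LysM-Cre tumours, 52 regions carried a peak in 3 of 3 libraries and in 0 of 3 Trem2-MKO libraries. The strongest spanned the lower-coordinate end of Psmd1 (chromosome 1, 86064063 to 86065099), a subunit of the 19S proteasome, with folds of 5.12, 4.86 and 4.18 over background in replicates 1, 2 and 3. Without strand, this end cannot be called the transcription start. The next lay outside genes, on chromosome 5 (61068654 to 61069120, 739.7 kb from G6pd2) and on chromosome 1 (88400174 to 88400725, 6.24 kb from Spp2, a liver-secreted phosphoprotein gene). The remaining 2 named by the rule were on chromosome 5 (104773083 to 104773704, 28.5 kb from Zfp951) and chromosome 3 (45914280 to 45915088, 479.7 kb from Pcdh10). Of the 52, 22 (42.3%) lay within a gene, near the 40.3% to 41.8% of all peaks of the LysM-Cre libraries. Chromosome 3 held the most, with 9, and also held 10.3% to 16.8% of all peaks of these libraries. Another 7 of the 52, counted separately, lay within 1 kb of a gene end, where 3.37% to 4.38% of all these peaks lay. These shares were not tested.

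In Trem2-MKO tumours, 23 regions showed the reverse pattern. The strongest lay within Naaladl2 (chromosome 3, 24197262 to 24197843), with folds of 6.52, 4.37 and 3.16 in replicates 1, 2 and 3. It was followed by regions within Herc3, a ubiquitin ligase gene (chromosome 6, 58845908 to 58846394), 347.2 kb from Acvr2a, an activin receptor gene (chromosome 2, 48466430 to 48466870), within Etl4 (chromosome 2, 19992073 to 19992556) and within Kmt2e, a gene of the MLL histone methyltransferase family (chromosome 5, 23434145 to 23434671). Of the 23, 10 (43.5%) lay within a gene, where 35.7% to 42.2% of all peaks of the Trem2-MKO libraries lay. Within 1 kb of a gene end were 4 of the 23, against 3.05% to 4.66% of all these peaks, and these shares were not tested.

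The count of 52 stood against 3.62 ± 2.04 (highest 10) in 100 draws of moved lists, and that of 23 against 0.24 ± 0.474 (highest 2). Moved lists break sharing of every kind, so they cannot test whether sharing follows genotype. Among trios of mixed genotype, LysM-Cre replicates 2 and 3 with Trem2-MKO replicate 1 had the most regions absent from the rest, 43. The next, LysM-Cre replicates 1 and 2 with Trem2-MKO replicate 1, had 20. The planned expectation, which treats union regions as if they could be empty in all libraries, was 637 and 41.3. The counts fell to 13 and 9 at a −log10 p of 5 or more and to 12 and 13 with the 4638 strongest peaks of each list, where Trem2-MKO no longer had the fewer. Leaving out LysM-Cre replicate 1, 2 or 3, which asks for 2 of 2 libraries, raised the first to 708, 457 or 626. Leaving out Trem2-MKO replicate 1, 2 or 3 raised the second to 124, 209 or 317.

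**Figure D3:**
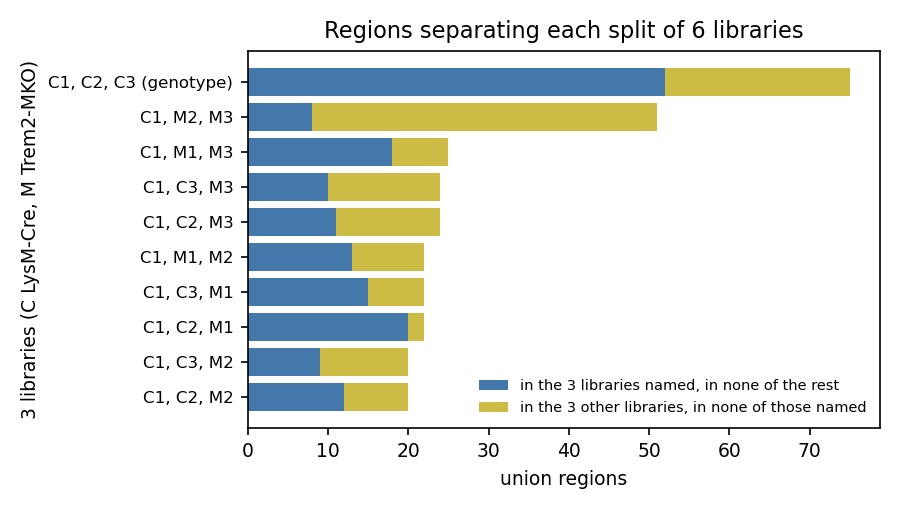
Number of union regions with a peak in all 3 libraries of one side and in none of the other side, for each of the 10 splits of the 6 libraries (C, LysM-Cre; M, Trem2-MKO; digits are replicates). The split by genotype gave 75 regions (52 and 23), and the next, C1 with M2 and M3, gave 51.

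H3K36ac peaks were not concentrated at gene ends in all tumours, so a peak list alone does not map the mark at active promoters. Gene-end windows took 3.64%, 3.37% and 4.38% of the peaks of LysM-Cre replicates 1, 2 and 3, and 3.05%, 4.66% and 3.19% of those of Trem2-MKO replicates. The genotypes did not differ beyond their spread (3.80 ± 0.524% against 3.63 ± 0.895%, n = 3 each, exact two-sided permutation p = 0.7), and the sign of the difference turned at a −log10 p of 5 or more, at a −log10 q of 2 or more (−0.886 percentage points) and without LysM-Cre replicate 3 or Trem2-MKO replicate 1 or 3. Moved lists, which keep the widths of the peaks, gave 2.88% to 3.71%. Against them the share was above all 100 draws in LysM-Cre replicate 3 (1.18 times) and Trem2-MKO replicate 2 (1.27 times), below all 100 in Trem2-MKO replicate 1 (0.835 times), and within the draws in the others.

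Summits, whose distances were looked at after the data were seen, lay near gene ends more often than chance in 5 of 6 libraries. Within 250 bp of a gene end, summits were 1.3, 1.36 and 1.72 times as frequent as in moved lists in LysM-Cre replicates 1, 2 and 3. The values for Trem2-MKO were 0.980, 2.09 and 1.59. In each library but Trem2-MKO replicate 1, the observed count exceeded the highest of the 100 draws. Between 2000 and 5000 bp the ratios were 0.848 to 0.930 in all 6 libraries.

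**Figure D4:**
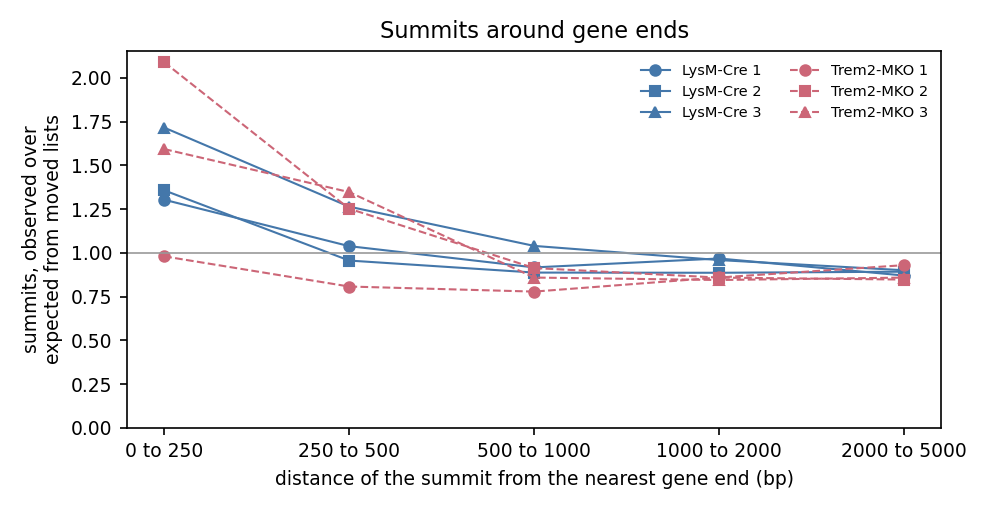
Ratio of observed summits to those expected from 100 draws of moved lists, by distance from the nearest annotated gene end in bp, for each library. Ratios were highest within 250 bp (0.980 to 2.09) and lay below 1 at 2000 to 5000 bp in every library.

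Few genes were marked, and no gene was marked in all tumours. Between 153 and 1065 of 21883 genes had a gene-end peak in a library. LysM-Cre replicates 1, 2 and 3 marked 721, 1065 and 925 genes, where moved lists marked 685, 1058 and 787. Trem2-MKO replicates 1, 2 and 3 marked 960, 341 and 153, against 1151, 270 and 143. A mark on a single gene is thus weak evidence that the gene carries H3K36ac. Across libraries, 3169 genes were marked in 1 library, 431 in 2, 42 in 3, 2 in 4 and 0 in 5 or 6. LysM-Cre tumours alone marked 12 genes in 3 of 3 libraries, counting a peak at any place in the gene-end windows. The 10 named by the rule were Psmd1, Arpc2 (a subunit of the actin-nucleating Arp2/3 complex), Mrpl39 (mitochondrial ribosome), Vax1 (a homeobox gene), Pik3r4 (the regulatory subunit of the class III PI3-kinase in autophagy), Ap5s1 (an adaptor of late endosomes), Crybb3 (a lens crystallin), Nsmf and Pnpla7, which are marked by a single region over the lower-coordinate end of Nsmf, within 1 kb of the higher-coordinate end of Pnpla7, and Zfp354a (a zinc-finger gene). For Mrpl39, Vax1 and Ap5s1, no region at the gene ends was shared by all 3 LysM-Cre libraries, so their marks came from peaks at different positions. Over gene bodies, 2 Trem2-MKO libraries had a peak in Psmd1 and 1 in Arpc2, and Pnpla7 turned, with 1 LysM-Cre and 2 Trem2-MKO libraries. Moved lists gave 1.71 ± 1.39 such genes (highest 6) and independence 1.39. The mixed trio of LysM-Cre replicates 2 and 3 with Trem2-MKO replicate 1 alone marked 5 genes.

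Trem2-MKO tumours alone marked 4 genes in 3 of 3 libraries: Zup1, a deubiquitinase gene, Dguok, the mitochondrial deoxyguanosine kinase gene, the gene model 0610010F05Rik, and Bst1, which encodes a surface ADP-ribosyl cyclase of myeloid and other cells. These calls depended on the window: Dguok had a peak in 2 of 3 LysM-Cre libraries with windows of 2.5 kb and over its body, 0610010F05Rik in 1 with windows of 2.5 kb and Zup1 in 1 over its body, while Bst1 had no peak in its body in any library. Moved lists gave 0.09 ± 0.288 such genes (highest 1) and independence 0.0922. The counts of 12 and 4 fell to 4 and 1 at a −log10 p of 5 or more and to 3 and 3 with the 4638 strongest peaks of each list, and with gene bodies in place of gene ends they became 185 and 7. Without LysM-Cre replicate 1, 2 or 3 the first was 98, 72 or 64, and without Trem2-MKO replicate 1, 2 or 3 the second was 15, 19 or 28.

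None of the gene lists separated the genotypes after adjustment (0 of 24 by exact two-sided permutation with Benjamini-Hochberg adjustment; smallest adjusted p = 0.764, and 0 at an unadjusted p under 0.05, which this test cannot reach with 3 against 3). In any library, 116 of 531 list genes (21.8%) and 16.7% of all genes were marked, a difference that was not tested. Moved lists gave a mean of 1.62 to 4.44 marks per gene list in LysM-Cre and 0.87 to 2.37 in Trem2-MKO. Many of the counts given below lie near these values. In the cytokine and growth factor list the 3 Trem2-MKO libraries all lay above the 3 LysM-Cre libraries, with 6 marks among 28 genes against 3, mean log2 odds ratios of 2.37 ± 1.16 and 0.36 ± 0.30 (n = 3 each, exact two-sided permutation p = 0.1, adjusted 0.764). Examples were Il33, an alarmin, and Tgfb2, each marked in 1 Trem2-MKO library at its ends, and Il12b and Ifnb1, each in 1 LysM-Cre library; over gene bodies the difference turned, with 2 LysM-Cre and 0 Trem2-MKO libraries for Il33 and 2 and 1 for Tgfb2, and the list as a whole had 16 marks in LysM-Cre and 9 in Trem2-MKO. The list of H3K36 and acetylation enzymes had 3 marks in Trem2-MKO and 4 in LysM-Cre, with Hdac1, a deacetylase, marked in 1 Trem2-MKO library and Hdac3 in 1 of each genotype. Its log2 odds ratios lay apart as well (1.38 ± 0.38 against 0.62 ± 0.29), but only through the 0.5 added to each cell, since Trem2-MKO replicate 3 marked 0 of its 28 genes. Complete separation by chance is nominally 10%, or 2.4 of 24 lists, and was 14% for random lists in simulated libraries; the added 0.5 lifts the odds ratio of libraries with few marked genes.

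Macrophage and monocyte genes had 6 marks in LysM-Cre and 4 in Trem2-MKO libraries, over 8 of 30 genes. Aif1 was marked in 1 LysM-Cre library, and the scavenger receptor Marco and the complement gene C1qc in 1 Trem2-MKO library each. In the list of lipid-associated macrophages, to which Trem2 belongs, Lgals3 (galectin-3) was marked in 2 LysM-Cre and 0 Trem2-MKO libraries and Gpnmb in 0 and 1 (3 and 2 marks, 20 genes). The list of TREM2 and PI3K signalling had 4 marks in LysM-Cre, including Card9 and Inpp5d, and 0 in Trem2-MKO. Over gene bodies this list had 14 marks in each genotype, with the Inpp5d difference turned, and genes of all kinds were marked 1.86 times as often in LysM-Cre libraries at their ends. Phagosome and lysosome genes had 2 marks in each genotype.

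Lymphocyte and granulocyte lists gave small counts on both sides. T and NK cell genes had 6 marks in LysM-Cre and 4 in Trem2-MKO, with Tcf7, a T cell memory factor, at 2 and 0 at its ends but 1 and 2 over its body, and Runx3 at 0 and 1. Checkpoint genes had 3 and 2, among them Nr4a3 and Btla in LysM-Cre and Pdcd1lg2 in Trem2-MKO. The 14 B and plasma cell genes had 5 marks in LysM-Cre, including Pax5 and Ms4a1, and 0 in Trem2-MKO, where the log2 odds ratio came wholly from the 0.5 added to each cell, so that its comparison says nothing about this list. Neutrophil genes had 6 and 2, with Csf3r, the G-CSF receptor, at 2 and 0. Dendritic cell genes had 2 and 1 and chemokines 3 and 0, Cxcl9 and Ccl3 among them.

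Hepatocyte genes had 5 marks in LysM-Cre and 3 in Trem2-MKO libraries, with the fibrinogen gene Fgg at 2 and 0 and the haem-binding Hpx at 0 and 2 at its ends and 1 and 0 over its body. Liver tumour genes had 5 and 1, including Afp, the fetal albumin homologue, and Lgr5 in 1 LysM-Cre library each. Cell cycle genes had 6 and 1, antigen presentation 4 and 1 (H2-Aa at 2 and 0), interferon response 3 and 4, glycolysis 4 and 2, lipid and bile acid metabolism 2 and 2, and stress genes 4 and 1. Endothelial genes had 3 and 1, stellate cell and fibroblast genes 1 and 0, cholangiocyte genes 0 and 1, and ubiquitous genes 3 and 1. Adjusted p was 0.764 or more for each of these lists. Of the 20 ubiquitous genes, 2, 1 and 0 were marked in LysM-Cre replicates 1, 2 and 3 and 1, 0 and 0 in Trem2-MKO replicates. Moved lists gave 2.34 and 1.25 marks for the 2 genotypes. The lists thus did not show the mark at these genes beyond moved peaks, although it is found mainly at promoters of active genes. Within single libraries, 0 of 144 two-sided Fisher's exact tests of a list against other genes passed adjustment (smallest adjusted p = 0.711) and 3 had an unadjusted p under 0.05: cytokines in Trem2-MKO replicate 2 (3 of 28 genes, p = 0.00921), B and plasma cells in LysM-Cre replicate 1 (3 of 14, p = 0.00988) and hepatocytes in LysM-Cre replicate 2 (4 of 25, p = 0.0312).

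Peaks were spread unevenly over the chromosomes, more by tumour than by genotype. Chromosome 3 held 16.8% of the peaks of LysM-Cre replicate 3 and 14.5% of those of Trem2-MKO replicate 2, but 9.88% to 10.5% in LysM-Cre replicates 1 and 2 and Trem2-MKO replicate 1, and 5.95% in Trem2-MKO replicate 3. Chromosome 14 held 1.37% of the peaks of LysM-Cre replicate 3 and 6.64% of those of Trem2-MKO replicate 3. The genotypes lay apart on 3 of 20 chromosomes, where chance gives 2: chromosome 5 (6.32 ± 0.136% in LysM-Cre, 6.0 ± 0.201% in Trem2-MKO), chromosome 18 (4.19 ± 0.105% and 3.97 ± 0.0615%) and X (0.723 ± 0.189% and 0.314 ± 0.154%). Each had an exact two-sided permutation p of 0.1 with n = 3 per genotype and an adjusted p of 0.667. On X, Trem2-MKO replicates 2 and 3 had only 16 and 10 peaks. Trem2-MKO replicate 1, at 0.492%, lay close to LysM-Cre replicate 1, at 0.509%. Density on X was low in every library, at log2 −3.00 to −4.93 relative to the median autosome. Without Trem2-MKO replicate 2 the genotypes lay apart on 12 chromosomes and without replicate 3 on 5, where 3 against 2 libraries give 4 by chance.

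**Figure D5:**
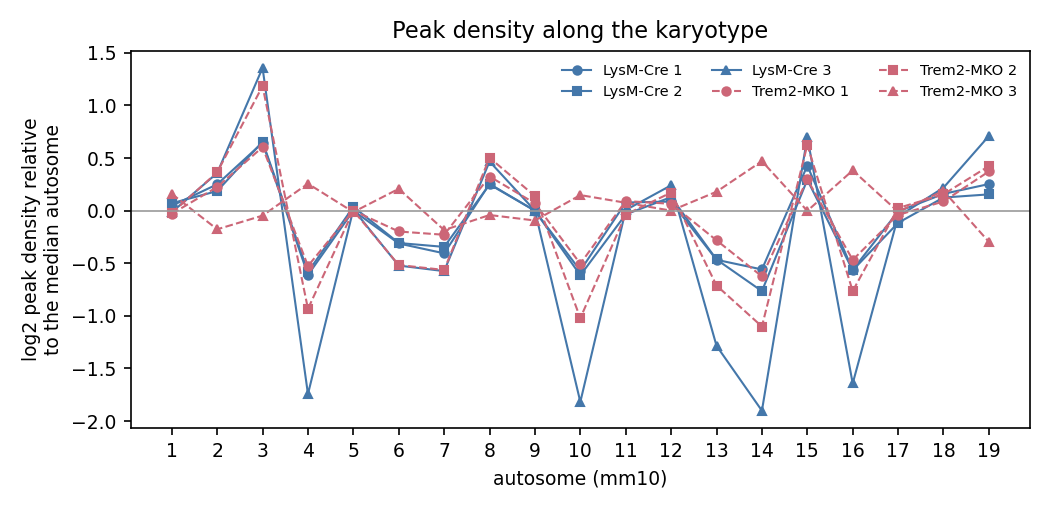
Log2 density of H3K36ac peaks on each autosome relative to the median autosome of the same library, for 3 LysM-Cre (solid) and 3 Trem2-MKO (dashed) libraries. In LysM-Cre replicate 3 the value was 1.36 on chromosome 3 and −1.90 on chromosome 14, and in Trem2-MKO replicate 3 it was −0.05 and 0.47.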

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

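The exact permutation test could not pass 0.05 with 3 libraries each, so the alternatives bear on sizes and signs. The excess of overlap within genotypes kept its sign in all settings run (0.208 to 0.551 percentage points), as did the difference in peak number. Without LysM-Cre replicate 1 the overlap difference was 0.365 percentage points. Another assignment of the libraries then gave one at least as large (exact one-sided permutation p = 0.2). Covered length changed sign with the 4638 strongest peaks per list (−0.0348 Mb), where the number of peaks is equal by construction; a comparison of peak numbers was void there. The gene-end share changed sign at a −log10 p of 5 or more (−0.381 percentage points), at a −log10 q of 2 or more (−0.886), and on leaving out single libraries (−0.132 to 0.677); the cause was not tested.

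Counts of specific regions and genes fell where fewer peaks entered and rose with wider windows or fewer libraries, as each setting's construction implies; the number of lists apart rose with fewer peaks, for a cause that was not tested. The LysM-Cre libraries, left out singly, moved LysM-Cre counts, and the Trem2-MKO libraries Trem2-MKO counts, by more than 1.5 times; Trem2-MKO replicates 2 and 3 also moved the chromosomes. At a −log10 p of 5 or more, LysM-Cre and Trem2-MKO regions were 13 and 9 and genes 4 and 1. At a −log10 q of 2 or more they were 11 and 7 regions and 3 and 1 genes, with 4 lists and 1 chromosome apart. With equal numbers of peaks they were 12 and 13 regions and 3 and 3 genes, with 5 lists apart. Summits ± 100 bp gave 32 and 15 regions, and windows of 2.5 kb gave 38 LysM-Cre genes. Gene bodies gave 185 and 7 genes and 4 lists apart. Without single libraries the ranges were 53 to 708 LysM-Cre and 24 to 317 Trem2-MKO regions, 12 to 98 and 4 to 28 genes, 0 to 1 regions in all libraries, 4 to 7 lists (4.8 by chance with 3 against 2) and 3 to 12 chromosomes (4 by chance). An overlap of 50% was run for pairs only, since each peak lies wholly within its union region. Trem2-MKO replicate 1 alone against LysM-Cre, added after seeing the data, gave 58 regions and 12 genes.

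Over gene bodies the difference in the share of marked libraries changed sign for 14 named genes: to −0.333 for Inpp5d, Tcf7, G6pc, Pnpla7, Ccl25 and Yap1, to 0.333 for Tgfb2, Ifih1, Nfkb1, Vwf and Hpx, and to 0.667 for Nr1h4, Il33 and Cd36; the cause was not tested. Deviations over 5 Mb bins correlated at −0.253, −0.462 and −0.583 for replicate numbers 1, 2 and 3, and at −0.450 to 0.561 across different numbers. These values do not tell whether tumours of the same number were handled together. With the number as a block, differences stayed at 8943 peaks, 4.22 Mb and 0.162 percentage points of gene-end share (exact two-sided sign-flip p = 0.5, 0.5 and 1), with 2 lists and 3 chromosomes apart. The median summit held 11 fragments in 4 libraries, and absence of a peak does not show absence of the mark.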

Other observations

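The tests in this part were chosen after the results they bear on had been seen, except the rotation of chromosome ends and the splits for gene lists and chromosomes, which were set before their results were seen. Regions found in more tumours lay closer to genes. The share of union regions at a gene end was 3.42% for regions of 1 library, 5.30% for regions of 2 libraries (228 of 4300, Fisher's exact p = 6.72e-10 against 1 library) and 6.95% for regions of 3 or more (23 of 331; exact 95% interval 4.46% to 10.2%; Fisher's exact p = 0.00201). Moved regions of the same widths gave 3.53%, 3.73% and 3.6%, with a highest draw of 6.65% for the last class. Regions in 4 or more libraries did not carry this further, with 1 of 26. Among the recurrent gene-end regions, chosen here after their values were seen, were the lower-coordinate end of Adgre1, which encodes the macrophage marker F4/80 (chromosome 17, 57358042 to 57358939; 1 LysM-Cre and 2 Trem2-MKO libraries), and a region next to Eomes, a transcription factor of T and NK cells (chromosome 9, 118486386 to 118487998; 1 and 2). Myh9 (1 and 2), Usp10 (2 and 1) and Chordc1 (2 and 1) were further examples.

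Further genotype-specific regions lay within genes outside the rule for naming; they were picked by hand after the values were seen and were not tested as a group. In LysM-Cre, one spanned part of Sox9, a ductal and progenitor transcription factor on the liver tumour and cholangiocyte lists (chromosome 11, 112784412 to 112785253). Others lay within Ets1 (chromosome 9, 32667683 to 32668418), the methyltransferase gene Kmt2c (chromosome 5, 25487747 to 25488171) and Daam1 (chromosome 12, 71882522 to 71883733). Among Trem2-MKO regions, further ones lay within the growth factor gene Nrg1 (chromosome 8, 31830790 to 31831568) and Epb41l3 (chromosome 17, 69107731 to 69108398).

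Splits of the 6 libraries can test these counts only coarsely, since 10 splits cannot give a share under 0.05. For regions, 1 of the 10 splits, the genotypes, gave as many as the real 75, and the highest other split gave 51. For gene-end genes, 1 of 10 gave the real 16, and the highest other gave 7. For gene lists lying apart, 8 of 10 splits gave at least the real 2, up to 4. For chromosomes lying apart, 4 of 10 gave at least the real 3, up to 7.

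The first pattern followed up was the sharing of peaks within a genotype. Broad regional density of peaks is argued against as its whole source: the observed difference of 0.373 percentage points lay above all 100 draws of moved lists, of which the highest gave 0.0787 even when scaled to the overlap seen between genotypes. A control shared by the libraries of a genotype may also produce common peaks, because the recovered control depth, an inferred value, was 106 fragments per 10 kb in the 3 LysM-Cre libraries and 144 in the 3 Trem2-MKO libraries. Among peaks whose background was the lowest of the library, mean overlap over expectation was 2.34 times as high within as between genotypes. The pair of Trem2-MKO replicates 2 and 3, at 10.4, raised this mean. The other pairs within genotypes gave 3.62 to 4.89, and pairs between genotypes 1.56 to 3.37. If each genotype had its own control, as the recovered depths would have it, genotype and control cannot be told apart.

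The second pattern was the small number of peaks in Trem2-MKO replicates 2 and 3. Fragments were placed at random at each library's recovered background, fragment length and scaling. The order of peak density was the same apart from 1 exchange, with a Spearman rho of 0.943 over 6 libraries at each of 3 gap settings (exact two-sided permutation p = 0.0167). Pearson r was 0.930 to 0.941 (exact two-sided permutation p 0.0153 to 0.0167). The 2 libraries farthest from the median of the random density were LysM-Cre replicate 2 and Trem2-MKO replicate 1. Without them r was 0.951 to 0.984 (exact two-sided permutation p 0.125 to 0.208). Trem2-MKO replicates 2 and 3 stayed in, so the relation was not examined without them. Random placement gave 10.3% to 43.0% of the observed density in Trem2-MKO replicate 2 and 5.87% to 22.9% in replicate 3. It gave 17.1% to 42.8% in LysM-Cre replicate 1, 12.5% to 37.3% in LysM-Cre replicate 3, 30.9% to 75.9% in LysM-Cre replicate 2 and 22.2% to 56.2% in Trem2-MKO replicate 1. Random placement used background, fragment length and scaling together, so the order of the libraries cannot be laid to depth alone. The fragment length was 340 bp in LysM-Cre replicate 2 and Trem2-MKO replicate 1. It was 390 bp in LysM-Cre replicates 1 and 3 and 410 bp in Trem2-MKO replicates 2 and 3. Immunoprecipitate over control depth was 0.747 and 0.530 in LysM-Cre replicate 2 and Trem2-MKO replicate 1. It was 0.582 and 0.576 in LysM-Cre replicates 1 and 3, so this ratio did not give the order. At gaps of 0, 50 and 100 bp, random placement did not account for most peaks of Trem2-MKO replicates 2 and 3. The same held for LysM-Cre replicates 1 and 3. The share rose with the gap in each library, and the gap of the peak caller was not known, so a larger share is not excluded. Placement was uniform, so local pileups from amplification were not covered. The knockout itself stays open: the remaining Trem2-MKO library had 29906 peaks, within the LysM-Cre range, but 1 library decides nothing.

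The third pattern was a profile of peak density over the autosomes that 5 tumours of both genotypes shared. Pairwise r across 19 autosomes, which are not independent replicates, was 0.972 to 0.988 among these libraries and −0.726 to −0.626 with Trem2-MKO replicate 3. Gene density is argued against, since its r with the profile lay between −0.0480 and 0.0867 in the 5 libraries, although it was −0.539 in Trem2-MKO replicate 3. Density stepped at chromosome ends: rotating the ends along the genome explained as much of the variance of 5 Mb bins in 0 of 501 rotations (0% as the highest over the 5 libraries, 18.0% in Trem2-MKO replicate 3). Real ends explained 26.1%, 28.3% and 24.0% in LysM-Cre replicates 1 and 2 and Trem2-MKO replicate 1, against highest rotations of 23.3%, 27.1% and 21.6%. In LysM-Cre replicate 3 and Trem2-MKO replicate 2 they explained 66.4% and 46.5%, against 60.5% and 42.5%. Whole-chromosome copy number common to the tumours, at a different tumour content in each, is thus a candidate explanation for the 5 libraries. Trem2-MKO replicate 3, where r was negative, did not share the profile. Peaks were called against a pooled control, and its effect on the sign of r was not tested, so this library does not decide. Whether the control carries the profile stayed open: r of density with the percent of peaks above the lowest background was 0.745 to 0.902 in 4 libraries, 0.0803 in Trem2-MKO replicate 2, which shared the profile, and −0.555 in replicate 3, and it is measured among called peaks only, so it does not decide.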
